A study of Mus musculus with 5 samples.

How the data were processed

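Total RNA from the striatum of wild-type (WT) and R6/1 mice on a mixed CBA and C57BL/6 background was sequenced, with 3 WT and 2 R6/1 libraries. R6/1 mice carry exon 1 of the human Huntington's disease gene with an expanded CAG repeat, given as 115 in the labels. Per the labels' protocols, ribosomal RNA was depleted and strand-specific libraries were made with random primers and PCR, so that RNA without a poly(A) tail was also sampled. Age, sex, litter, time of collection and sequencing batch are not given in the sources used here.

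Raw read counts per Ensembl gene were deposited by the authors, per the file headers, in 1 table of 26369 genes with 5 libraries. The submitters' processing notes list CASAVA 1.8.2, TopHat 1.4.1, HTSeq 0.5.4p3 and DESeq2 1.0.19 and the mouse build mm9. The Ensembl release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. The table also holds a signal made by the authors by dividing counts by 1 size factor per library, and the same signal per kb of gene length, per the file headers. The normalized values were used only to read back the size factors. The log2 fold changes, p-values and adjusted p-values of the authors' own comparison were deposited in the same table and are quoted only where the authors' deposited table is named. No row lacked a gene identifier and no per-sample column was left unmapped. No coordinates are given, because no annotation of the authors' build was used here.

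Total counts per library were 23046266, 19630036 and 22963042 for WT replicates 1 to 3 and 34379064 and 29871306 for R6/1 replicates 1 and 2. Every R6/1 library was deeper than every WT library, so depth and genotype go together. A single count stood for 0.0277 to 0.0527 CPM, the count scaled to the library total. Intervals for low counts are exact Clopper-Pearson intervals at the 95% level and, like floors of 3 counts, cover counting error only, since PCR copies are not independent molecules.

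Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM normalization, the filterByExpr filter (minimum count 10, minimum total 15) and a design of genotype alone. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and 17202 genes were tested. CPM values are TMM-normalized and are given as mean ± SD with n = 3 for WT and n = 2 for R6/1. Log2 fold changes are R6/1 over WT with the standard error (SE) implied by the F statistic. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per gene of 11.5 to 20.

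Gene lists for striatal cell types, neuronal functions, stress responses, neighbouring tissue and sample make-up were fixed before the data were examined, 28 in all. They were chosen to fit striatal tissue and Huntington's disease, so earlier knowledge of the disease may have shaped their members. Some genes, such as Scn4b, Cnr1 and Homer1, belong to several lists, so the lists are not independent. Of their 663 entries, 646 were found in the table by symbol or, through a reference table of gene names, by Ensembl identifier, and 2 that repeated a gene of the same list under another symbol were counted once. Each list was compared with all other tested genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, two-sided and adjusted over the 28 lists. The calls were repeated with an estimated correlation and with fry, which tests a list without comparing it with other genes. Genes named in the text follow a rule fixed at the same time. It takes Htt, 8 striatal marker genes, the 6 largest increases and 6 largest decreases among called genes with a mean log2 CPM of at least 1, no overlap between the groups and a symbol that is not a predicted or clone-style name. It adds the 3 smallest p-values in each direction under the same conditions, and up to 3 called members of each list. From a list with no called member it takes the member with the highest mean log2 CPM. The sex-linked list is treated apart, with values given per library to check the make-up of the samples. Some genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen.

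The steps were tested on simulated data for this comparison, with 200 of 17202 genes changed in 10 simulations. With each gene's own dispersion, the test recovered 33.1% of genes changed 1.5-fold, 62.4% of those changed 2-fold and 87.9% of those changed 4-fold. Unchanged genes made up 9.68% of the calls, above the nominal level, against 4.35% when the simulated dispersions followed the fitted trend. Far more genes were called in the data (3882) than were changed in the simulations, which moves the p-value cut of the adjustment. The recovered and false shares therefore need not hold for the data. The alternatives were RLE, upper-quartile and no normalization, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, robust empirical Bayes, a test against a fold change of 1.2, a stricter threshold, and leaving out each library in turn. Leaving out WT replicates 1 and 2, a covariate of choroid plexus markers and thinned counts were added after seeing the data, the thinning before any of its results was seen.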

Results

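RNA of the striatum, the brain region most affected in Huntington's disease, was compared between libraries from WT mice (n = 3 libraries) and from R6/1 mice (n = 2 libraries), which carry exon 1 of the human disease gene with an expanded CAG repeat. The total per library ranged from 19630036 to 34379064 counts. The comparison asks which striatal transcripts differ in the disease model. Mouse Htt (ENSMUSG00000029104), the endogenous counterpart of the disease gene, was at 354 ± 3.46 CPM in WT and 369 ± 3.08 CPM in R6/1. Its log2 fold change was 0.06 with an SE of 0.06 (edgeR adjusted p = 0.481). Counts over the mouse gene do not measure the human transgene and do not check the genotype labels. Xist was at 1273 to 1541 CPM in the 5 libraries, and the Y-linked genes Ddx3y and Eif2s3y had at most 3 counts in any of them. Uty, also Y-linked, had 14, 8 and 13 counts in WT replicates 1 to 3 and 30 and 19 in R6/1 replicates 1 and 2. In CPM, Uty ranged only from 0.421 to 0.832 over the libraries. Xist was high and Ddx3y and Eif2s3y were nearly uncounted in both groups, so these genes show no difference in sex between the groups.

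Transcripts that mark the medium spiny neuron, the principal projection neuron of the striatum, were lower in both R6/1 libraries than in every WT library. Ppp1r1b (ENSMUSG00000061718), which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, was at 626 ± 58.0 CPM in WT and 172 ± 9.68 CPM in R6/1, 3.64-fold lower. Pde10a (ENSMUSG00000023868), a striatal cyclic nucleotide phosphodiesterase, fell from 2606 ± 216 to 491 ± 0.717 CPM. Scn4b, a sodium channel beta subunit, was 14.7-fold lower and Ryr1, a calcium release channel, 15.4-fold lower. In all, 3882 of 17202 tested genes were called by edgeR, 22.6% of them, with 2210 lower and 1672 higher in R6/1. A change of at least 2-fold was measured for 775 of the lower and 270 of the higher genes.

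**Figure D1:**
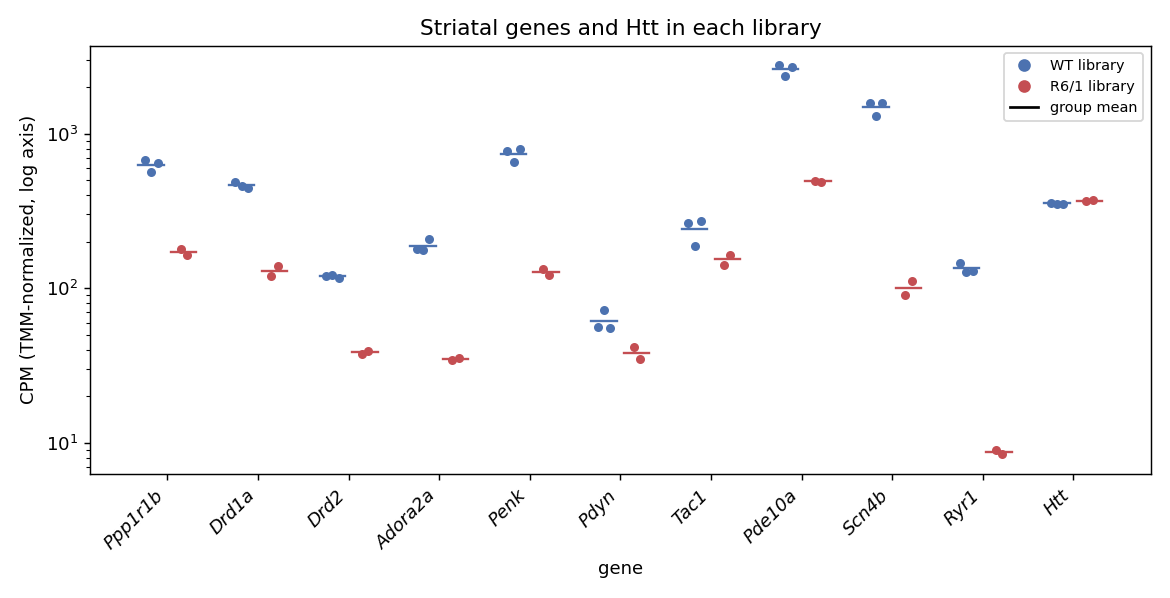
TMM-normalized CPM on a log axis for 10 striatal genes and Htt, with 1 point per library (3 WT, 2 R6/1) and a line at each group mean. In each of the 10 striatal genes both R6/1 libraries lie below every WT library, while Htt differs by 1.04-fold.

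All 35 members of the medium spiny neuron list fell, with a median log2 fold change of -1.49, and 35 also fell when adjusted over the list alone. camera called the list lower than other genes (adjusted p = 4.09e-128), and adjusted p = 0.0239 with an estimated correlation. Ryr1 had a log2 fold change of -3.94 (SE 0.10, adjusted p = 2.19e-05) and Scn4b one of -3.88 (SE 0.14, adjusted p = 8.47e-05). Both projection pathways were represented among the falls. Drd2, Adora2a and Penk of the indirect pathway list also belong to the medium spiny neuron list. So do Drd1a, Pdyn and Tac1 of the direct pathway list, so the pathway lists are not separate support. Of the 8 tested markers of the indirect pathway, whose neurons carry the D2 dopamine receptor, 5 fell and 3 did not pass, with 6 falls when adjusted over the list alone. The median was -1.76 (camera adjusted p = 7.88e-28, and adjusted p = 0.0239 with an estimated correlation). Penk, the enkephalin precursor, fell 5.80-fold from 740 ± 74.3 to 128 ± 8.57 CPM, Adora2a, the adenosine A2a receptor, fell 5.40-fold and Drd2 fell 3.09-fold. Of the 11 markers of the direct pathway, whose neurons carry the D1 dopamine receptor, 6 fell, 1 rose and 4 did not pass, with 7 falls and 1 rise when adjusted over the list alone. Their median was -0.37 (camera adjusted p = 0.000257, and adjusted p = 0.118 with an estimated correlation). Drd1a, the file's symbol for the D1 receptor gene, fell 3.59-fold and Chrm4 fell 2.77-fold. Pdyn, the dynorphin precursor, fell by 0.68 on the log2 scale (adjusted p = 0.0170) and Tac1, the substance P precursor, by 0.66 (adjusted p = 0.0295). The call for Pdyn was lost without R6/1 replicate 1 (adjusted p = 0.0602) or 2 (adjusted p = 0.130). With 1 library left out, the call for Tac1 was kept only without WT replicate 2, and its edgeR adjusted p was 0.0687 to 0.177 without each of the other libraries. Without R6/1 replicates 1 and 2 in turn, 2 and 3 direct pathway markers fell. No test compared the pathways with each other.

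Of 40 ion channels, 30 fell and 10 did not pass, with a median of -0.66 and 31 falls when adjusted over the list alone (camera adjusted p = 1.04e-28, and adjusted p = 0.0239 with an estimated correlation). Ano3 fell 4.42-fold and Kcnip2, an auxiliary subunit of Kv4 potassium channels, 2.52-fold. Of 30 receptors for neuropeptides, monoamines, opioids and acetylcholine, 14 fell, 1 rose and 15 did not pass, with 15 falls and 2 rises when adjusted over the list alone. Their median was -0.77 (camera adjusted p = 3.20e-14, and adjusted p = 0.0239 with an estimated correlation). Cnr1, the cannabinoid receptor, fell 5.06-fold, Oprd1 3.72-fold and Htr2a 3.58-fold. Of 37 genes for glutamate receptors and the postsynaptic density, 19 fell and 18 did not pass, with 22 falls when adjusted over the list alone. Their median was -0.37 (camera adjusted p = 1.17e-11, and adjusted p = 0.135 with an estimated correlation). Homer1, a postsynaptic scaffold, fell 2.41-fold, and the glutamate receptor Grik2 fell 2.36-fold. Among 29 immediate early genes, which respond to neuronal activity, 12 fell and 17 did not pass, with 13 falls when adjusted over the list alone. The median was -0.65 (camera adjusted p = 2.32e-06, and adjusted p = 0.0613 with an estimated correlation). Dusp6 fell 1.99-fold and Ier5 1.84-fold. Without R6/1 replicate 1 or 2, 6 of these genes fell.

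Genes shared by most neurons were not called as a list. Of 24 pan-neuronal genes, 3 rose, 5 fell and 16 did not pass, with 4 rises and 5 falls when adjusted over the list alone and a median of -0.04 (camera adjusted p = 0.965). Syp, a synaptic vesicle protein, was at 203 ± 61.0 CPM in WT and 436 ± 21.1 CPM in R6/1 (adjusted p = 0.0119). Its call was lost without R6/1 replicate 1 (adjusted p = 0.0805) or 2 (adjusted p = 0.0654). Of 21 genes for GABA synthesis, transport and receptors, 5 fell, 1 rose and 15 did not pass, with 7 falls and 1 rise when adjusted over the list alone (median -0.0038, camera adjusted p = 0.358). Gabrd, a GABA-A receptor subunit, fell 3.27-fold, and Gad1, which makes GABA, fell by 0.50 on the log2 scale. The call for Gad1 was lost without R6/1 replicate 1 (adjusted p = 0.0803). Without WT replicate 3, R6/1 replicate 1 and R6/1 replicate 2 in turn, 2, 1 and 0 pan-neuronal genes fell, and 3, 1 and 3 GABA genes. Without R6/1 replicates 1 and 2 in turn, 0 and 1 pan-neuronal genes rose, and without WT replicate 2, 3 GABA genes rose. Without normalization, 5 pan-neuronal genes rose and 3 fell, and 2 GABA genes rose and 3 fell. Of 14 tested interneuron markers, 7 fell and 7 did not pass, with 8 falls when adjusted over the list alone. Their median was -0.75 (camera adjusted p = 6.28e-05, and adjusted p = 0.118 with an estimated correlation). Slc5a7, the choline transporter of cholinergic neurons, fell 3.49-fold, Chat 2.93-fold and Nos1 1.68-fold. Without R6/1 replicate 1 or 2, 4 interneuron markers fell. Of 27 striatal transcription factors, 9 fell, 2 rose and 16 did not pass, with 11 falls and 2 rises when adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.00939, and adjusted p = 0.323 with an estimated correlation). Bcl11b, a regulator of medium spiny neuron differentiation, fell 1.79-fold, Rarb 2.06-fold and Npas2 2.52-fold. Without R6/1 replicate 1 or 2, no striatal transcription factor rose in edgeR.

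**Figure D2:**
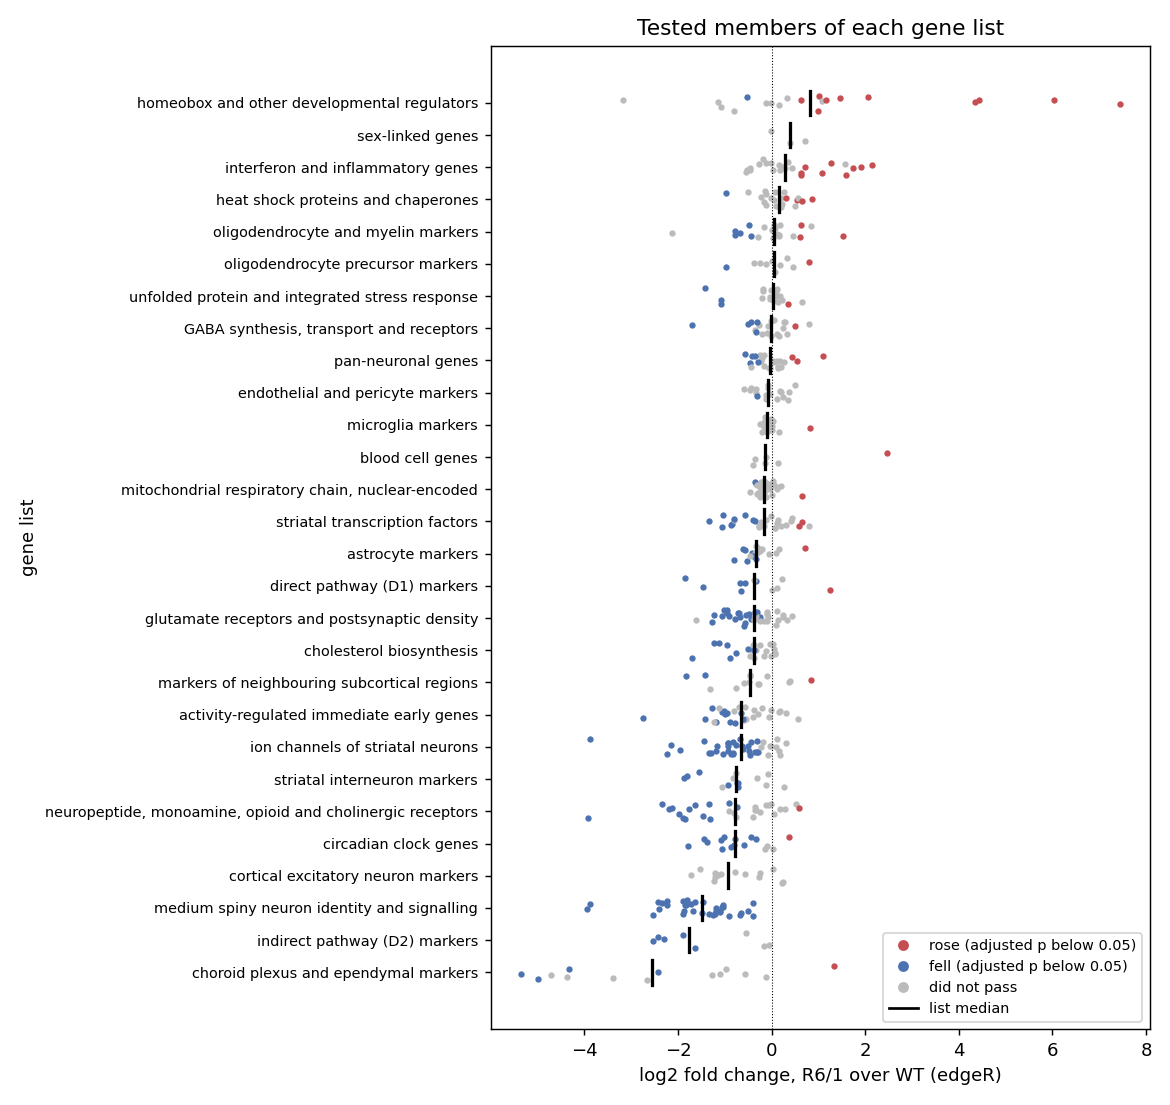
Log2 fold change (R6/1 over WT, edgeR) of every tested member of the 28 gene lists, 1 point per gene, red for genes that rose, blue for genes that fell and grey for genes that did not pass, with a bar at each list median. The medium spiny neuron list lies wholly below 0 with a median of -1.49, while the pan-neuronal list has a median of -0.04.

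Among glial and vascular lists, only the astrocyte list was called by camera. Of 18 astrocyte markers, 7 fell, 1 rose and 10 did not pass, with 10 falls and 1 rise when adjusted over the list alone. Their median was -0.33 (camera adjusted p = 0.0112, and adjusted p = 0.542 with an estimated correlation). The list was not called by fry (adjusted p = 0.0772). Slc1a2, the main glial glutamate transporter, fell 1.52-fold and the bicarbonate transporter Slc4a4 1.75-fold, while Gfap, an intermediate filament, rose by 0.71 on the log2 scale (chosen after its values were seen). No astrocyte marker rose in edgeR without R6/1 replicate 1 or with a choroid plexus covariate. With R6/1 replicate 1 or 2 left out, 2 astrocyte markers fell, and without WT replicate 3 or without normalization, 4 fell. The oligodendrocyte list had 3 rises, 5 falls and 13 members that did not pass, with 4 rises and 6 falls when adjusted over the list alone (median 0.05, camera adjusted p = 0.738). Sox10 rose 2.88-fold. No oligodendrocyte marker fell in edgeR without R6/1 replicate 1 or 2, 1 fell without WT replicate 3 and 2 without WT replicate 1. Without R6/1 replicate 1 or 2, 1 rose, and without normalization 5 rose and 1 fell. The 10 precursor markers had 1 rise and 1 fall, with 2 of each when adjusted over the list alone (median 0.05, camera adjusted p = 0.965). The 22 microglia markers had 1 rise, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.965). The 18 endothelial and pericyte markers had 1 fall in edgeR and 0 when adjusted over the list alone, where 5 had an unadjusted p below 0.05 and DESeq2 called 4 over all genes (median -0.08, camera adjusted p = 0.967). Without WT replicate 2, 3 of them rose and 3 fell, and without normalization 2 rose and 0 fell by edgeR. For the oligodendrocyte precursor list the median and the direction of the camera statistic differed in sign, as they did for the pan-neuronal, microglia, endothelial, unfolded protein and blood cell lists, none of which was called. The oligodendrocyte list had a mean of -0.04, below 0, with a median above it.

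Circadian clock genes also differed. Of 16 members, 12 fell, 1 rose and 3 did not pass, the same counts as when adjusted over the list alone. The median was -0.78 (camera adjusted p = 2.98e-08, and adjusted p = 0.121 with an estimated correlation). Dbp, a clock-controlled transcription factor, fell 2.70-fold from 111 ± 8.19 to 40.9 ± 4.27 CPM. The repressor Nr1d1 fell 2.59-fold and Hlf fell 2.02-fold. Without R6/1 replicate 1, 7 clock genes fell. Of 23 tested genes of cholesterol synthesis and its control, 8 fell and 15 did not pass, with 11 falls when adjusted over the list alone. Their median was -0.38 (camera adjusted p = 0.000610, and adjusted p = 0.118 with an estimated correlation). The enzyme genes Sc4mol and Fdft1 fell 2.34-fold and 2.18-fold, and Insig1, a regulator of sterol synthesis, fell 1.92-fold. Without WT replicate 3, R6/1 replicate 1 and R6/1 replicate 2 in turn, 5, 3 and 4 of these genes fell. Of 25 tested interferon and inflammatory genes, 9 rose and 16 did not pass, the same counts as when adjusted over the list alone. Their median was 0.28 (camera adjusted p = 0.00218, and adjusted p = 0.118 with an estimated correlation). Irf7 rose 4.42-fold and Oasl2 3.75-fold from less than 1 CPM. Without WT replicate 3 or R6/1 replicate 1, 5 of these genes rose, and 3 without R6/1 replicate 2.

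Some developmental regulators that were nearly uncounted in WT were counted in both R6/1 libraries. Of 20 tested members of the homeobox and developmental list, 10 rose, 1 fell and 9 did not pass, with 10 rises and 2 falls when adjusted over the list alone. The median was 0.82 (camera adjusted p = 4.05e-05, and adjusted p = 0.142 with an estimated correlation). Setting the 3 genes of 1 to 3 WT counts at the lower bound of their intervals could not move this median, since all 3 bounds lie above it. Wt1 had 1 count over the 3 WT libraries and 240 over the 2 R6/1 libraries, a ratio of 226 with a 95% counting interval of 40.2 to 8960. Lmx1b had 3 and 228 counts, a ratio of 71.5 with an interval of 24.2 to 349. Irx5 had 4 and 93 counts, a ratio of 21.9 with an interval of 8.27 to 82, and was at 1.38 ± 0.0729 CPM in R6/1. Without R6/1 replicate 1 or 2, 5 members of the list rose. Without WT replicate 3, 7 rose and 3 fell, and without WT replicate 1, WT replicate 2 or R6/1 replicate 2, 0 fell by edgeR.

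Markers of neighbouring tissue differed between libraries of the same group. The choroid plexus transcript Ttr, chosen after its values were seen, was at 3466 and 3341 CPM in WT replicates 1 and 2, but at 69.4 CPM in WT replicate 3 and at 90.5 and 21.1 CPM in the R6/1 libraries. The choroid plexus and ependymal list had 4 falls, 1 rise and 9 members that did not pass, with 9 falls and 1 rise when adjusted over the list alone. Its median was -2.55 (camera adjusted p = 0.0341, and adjusted p = 0.814 with an estimated correlation). The list was not called by fry (adjusted p = 0.314). The camera call was lost without WT replicate 1 (adjusted p = 0.119, 1 fall), without WT replicate 2 (adjusted p = 0.144, 1 fall) and without R6/1 replicate 2 (adjusted p = 0.131, 0 falls by edgeR). It was kept without WT replicate 3 (adjusted p = 1.69e-16, 9 falls) and without R6/1 replicate 1 (adjusted p = 0.000423, 2 falls). With WT replicates 1 and 2 both left out, the median of this list was -0.24, that of the medium spiny neuron list -1.55 with 35 falls, that of the ion channels -0.69, that of the developmental list 1.26 with 8 rises and that of the clock genes -0.64 with 8 falls. That setting called 3481 genes, 2693 of them also called in the same direction with all libraries, but its lone WT library is assumed to vary like the R6/1 pair. With the mean of 8 choroid plexus markers as a covariate, 1653 genes were called, 1538 of them shared in the same way, 32 medium spiny neuron genes fell, 5 developmental genes rose and 7 clock genes fell. The medians of these lists were then -1.60, 1.07 and -0.64, against -1.49, 0.82 and -0.78 without the covariate. Slc17a7, the vesicular glutamate transporter of cortical neurons, ranged from 22.6 to 136 CPM among WT libraries and was at 50.0 and 18.4 CPM in R6/1. None of the 14 cortical markers passed in edgeR by either adjustment, where 1 had an unadjusted p below 0.05 and DESeq2 called 1 and limma-voom 0 (median -0.93, camera adjusted p = 0.373). Without WT replicate 1 the cortical list was called lower (adjusted p = 0.00184), as it was without R6/1 replicate 1 (adjusted p = 0.0390). The 14 tested markers of neighbouring subcortical regions had 1 rise and 2 falls by either adjustment (median -0.46, camera adjusted p = 0.506).

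**Figure D3:**
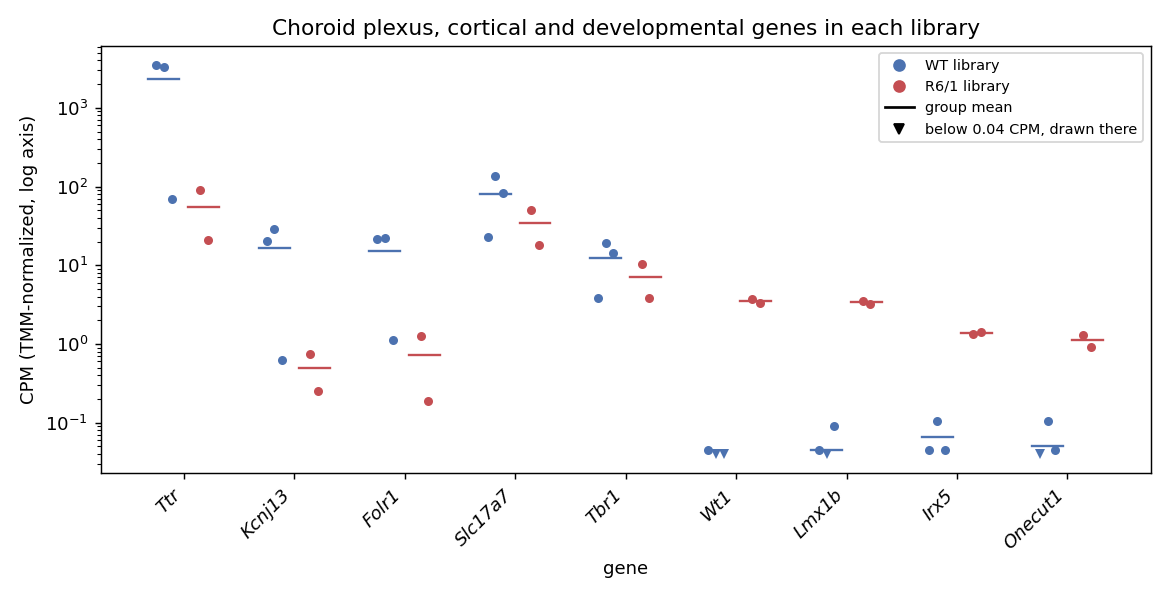
TMM-normalized CPM on a log axis for choroid plexus (Ttr, Kcnj13, Folr1), cortical (Slc17a7, Tbr1) and developmental genes (chosen after their values were seen), with 1 point per library and a line at each group mean; triangles mark values below the lowest drawn level, and a mean below it is not drawn. WT replicates 1 and 2 stand apart in the choroid plexus genes, with Ttr at 3466 and 3341 CPM, whereas the developmental genes separate the genotypes.

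The remaining lists were not called. The 23 heat shock and chaperone genes had 4 rises and 1 fall by either adjustment (median 0.15, camera adjusted p = 0.108), with Hsp90aa1 rising 1.45-fold. Its call was lost without R6/1 replicate 1 (adjusted p = 0.0646) or 2 (adjusted p = 0.0676). Rises numbered 1 without WT replicate 3, 0 without R6/1 replicate 1 or 2 and 8 without normalization. The list itself was called higher without WT replicate 2 (adjusted p = 0.00506), without a filter (adjusted p = 0.0401) and with WT replicates 1 and 2 both left out (adjusted p = 0.00513, 7 rises). The 20 genes of the unfolded protein and integrated stress response had 1 rise and 3 falls by either adjustment (median 0.04, camera adjusted p = 0.965), with Atf6 falling 2.11-fold. With R6/1 replicate 1 or 2 left out, 1 of these genes fell. Of 38 nuclear genes of the respiratory chain, 1 rose, 1 fell and 36 did not pass, and 0 passed when adjusted over the list alone with edgeR p-values, where 14 had an unadjusted p below 0.05 and DESeq2 called 4 and limma-voom 3 over all genes (median -0.15, camera adjusted p = 0.180). That list was called lower without R6/1 replicate 2 (adjusted p = 0.00459) and with WT replicates 1 and 2 both left out (adjusted p = 0.042, 4 falls). Without WT replicate 2 alone, 7 of its genes fell (camera adjusted p = 0.189), and without each other single library 0 fell by edgeR. Of 6 tested blood cell genes, 1 rose, S100a9, and 0 when adjusted over the list alone, where 1 had an unadjusted p below 0.05 and DESeq2 called 1 and limma-voom 0 over all genes (median -0.13, mean 0.27, camera adjusted p = 0.824). With 1 library left out, the call for S100a9 was kept only without R6/1 replicate 2, and its adjusted p was 0.409 without R6/1 replicate 1 and 0.0640 to 0.119 without 1 of the WT libraries. None of 3 tested sex-linked genes passed in edgeR by either adjustment, 0 had an unadjusted p below 0.05, and DESeq2 and limma-voom called 0 (median 0.39, camera adjusted p = 0.731).

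Across all tested genes, the 6 largest decreases under the naming rule were Wnt8b, Gpx6, Cyp2a5, Sec14l3, Tmprss6 and Tmem72. Gpx6, a glutathione peroxidase, had 752 counts over the WT libraries and 4 over the R6/1 libraries. Wnt8b, a secreted signalling protein, had 307 and 1, a ratio of WT to R6/1 of 326 with an interval of 58.1 to 12900. Cyp2a5 was at 14.3 CPM in WT replicate 1 but at 0.843 and 1.08 CPM in the other WT libraries, and Tmem72 was at 15.8 and 25 CPM in WT replicates 1 and 2 but at 0.812 CPM in WT replicate 3 and at 0.250 and 0.510 CPM in R6/1. The mean log2 CPM of 8 choroid plexus markers was 5.43 and 5.72 in WT replicates 1 and 2, 1.35 in WT replicate 3 and 1.75 and 0.20 in R6/1, high in the same libraries as Tmem72 but not as Cyp2a5. The calls for Cyp2a5 (adjusted p = 0.207 and 0.168) and Tmem72 (adjusted p = 0.183 and 0.156) were lost without R6/1 replicates 1 and 2 in turn, and that for Tmem72 also without WT replicate 1 (adjusted p = 0.0611). The 6 largest increases were Sfmbt2, Klhl14, Rpl3, Tpx2, Tmc3 and Greb1. Sfmbt2, a Polycomb-group protein, rose 6.90-fold from 4.81 ± 0.940 to 33.1 ± 0.504 CPM (log2 fold change 2.79, SE 0.16, adjusted p = 0.000121). Tpx2, a mitotic spindle protein, rose 4.76-fold. Rpl3, a ribosomal protein gene, was at 2.71 CPM in WT, and its value is uncertain because near-identical copies could share its reads. Gprasp2 rose 2.50-fold from 141 ± 9.61 CPM.

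The groups did not overlap at 9308 of the tested genes, 54.1%, where interchangeable libraries would give 20% on average over splits. Genes vary together across libraries, so a single split can lie far from 20%. The share was not computed for other splits, so it does not test the genotype. The authors' deposited table lists 5443 genes at an adjusted p below 0.05, 2782 of them lower, and 3862 of the 3882 genes called here are among them in the same direction. Without normalization beyond the library totals, the median of all tested genes moved to 0.11 and lower genes made up 34.4% of the calls in place of 56.9%. Leaving out 1 library left between 1088 and 4853 called genes, with 2517 without WT replicate 3, 1152 without R6/1 replicate 1 and 1088 without R6/1 replicate 2. In the fits without an R6/1 library, the remaining one is assumed to vary like WT. Of 19 counts of 1 or 2 calls in a list and direction, 16 were 0 without at least 1 library.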

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

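The alternatives with the choroid plexus covariate, with WT replicates 1 and 2 left out and with thinned counts were chosen after seeing the data. The count of 3882 called genes stayed within 1.5 times under RLE and upper-quartile normalization, no normalization, both filters, DESeq2, limma-voom and robust empirical Bayes (3799 to 4931). It was 3481 with WT replicates 1 and 2 left out, a fit whose lone WT library is assumed to vary like the R6/1 pair. It was 1771 (1223 lower, 548 higher) in a test against a fold change of 1.2 and 1402 (995 lower, 407 higher) at an adjusted p below 0.01, both stricter by construction. It was 1653 (1120 lower, 533 higher) with the choroid plexus covariate, and the cause was not tested. Without normalization, 3237 genes were higher. Leaving out 1 library at a time gave 1088 to 4853 called, 776 to 2576 lower and 280 to 2277 higher, with fewer samples in each fit. The count of 15 called lists was 4 with an estimated correlation and 13 to 16 under the other alternatives, and with 1 library left out it was 15 to 16. All 86 named genes kept their direction under DESeq2, RLE, no filter and each library left out. Most of these genes were named because they were called in these same data, so their direction could hardly change. DESeq2, RLE and no filter changed no call among them, while 9, 3 and 7 calls were lost without WT replicates 1 to 3, and 23 and 22 without R6/1 replicates 1 and 2.

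Medians changed sign only in lists that camera did not call with all libraries, and the cause was not tested. Without normalization the GABA median was 0.11, the pan-neuronal 0.075, the microglia 0.028 and the endothelial 0.042. Under RLE the GABA median was 0.0025. With WT replicates 1 and 2 left out, the oligodendrocyte median was -0.029 and the blood cell median 0.41. With the choroid plexus covariate, the oligodendrocyte median was -0.062 and the subcortical 0.14. With 1 library left out at a time, medians ranged from -0.11 to 0.019 for GABA, -0.15 to 0.051 for pan-neuronal, -0.013 to 0.12 for oligodendrocyte and -0.045 to 0.10 for precursor genes. They ranged from -0.12 to 0.012 for microglia, -0.10 to 0.015 for endothelial, -0.026 to 0.063 for unfolded protein response, -0.40 to 0.12 for blood cell and -0.13 to 0.60 for sex-linked genes. No paired analysis was possible because the labels number the groups without shared replicate numbers.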

Other observations

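The tests on neighbouring tissue, cell-cycle genes, protocadherins and expression level, and the genes named in the first paragraph, were chosen after values were seen, and thinning was added after seeing the data but before any of its results. Among 48 untested members of the developmental list, 31 had a higher and 17 a lower mean CPM in R6/1, and 17 of the 48 had at most 3 counts in each group. For 16 of the 48, every WT library had 0 counts, and 10 of these were counted in both R6/1 libraries. In the reverse direction, 5 had 0 counts in both R6/1 libraries, and 0 of these were counted in all 3 WT libraries. Hoxc5 had 34 counts in R6/1, at least 10.7-fold higher against a floor of 3 counts over the WT libraries, Hoxc4 at least 7.53-fold and Nkx6-1 at least 5.96-fold. That floor leaves out the counting error of R6/1, and the lower 95% counting limits of these ratios were 8.21, 5.67 and 4.39. The non-coding gene C130021I20Rik had 7 counts over the WT libraries and 566 over the R6/1 libraries, a ratio of 76.1 with a 95% counting interval of 36.7 to 190.

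A shared rise of protocadherin beta genes was tested as a hypothesis prompted by Pcdhb2. Without it, 15 of 21 tested members rose and none of the 21 fell by edgeR, with a median log2 fold change of 0.764 (camera adjusted p = 3.17e-11, and adjusted p = 0.231 with an estimated correlation). These clustered genes are similar in sequence, so shared reads may contribute. A shared rise of cell-cycle genes was tested without Tpx2, Cdc45, Cdca2 and Recql4. Of 87 tested members, 16 rose and 4 fell, with a median of 0.123 (camera adjusted p = 0.0464, and adjusted p = 0.508 with an estimated correlation). Over all 17202 tested genes, 22.6% were called, 1672 higher and 2210 lower. Calls were thus about as frequent among cell-cycle genes as among all genes, and only their direction differed. The camera p-values in this paragraph were adjusted over the protocadherin and cell-cycle lists alone, apart from the 28 lists fixed beforehand. The hypothesis that falls are more frequent among highly expressed genes was not borne out. Among called genes 62.9% fell in the highest quartile of expression and 65.9% in the lowest, a difference of -2.95 percentage points (95% interval -7.76 to 1.86), with lower shares between them (53.1% and 47.9%).

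The fall of the medium spiny neuron list was weighed against a lower share of striatal neurons and against depth. The pan-neuronal median lay 1.45 above that of the medium spiny neuron list (bootstrap interval over genes 1.03 to 1.86). The bootstrap intervals here and in the next paragraph treat genes as independent and leave out the spread between libraries. With 1 library left out, the pan-neuronal median ranged from -0.15 to 0.051 and the medium spiny neuron median from -1.59 to -1.4. Glial medians lay between -0.33 and 0.05. These medians argue against a lower share of all neurons as the whole cause. After thinning every library to the smallest total, the list's median was -1.49 (-1.51 to -1.48 over 10 thinnings). Thinning keeps each library's expected proportions, so this median could hardly move and does not decide on depth. After thinning, 90.2% of all called genes were still called in the same direction. The larger number of counts in R6/1 therefore does not account for most calls. Other differences that go with depth were not tested. The R6/1 genotype is a candidate explanation, as a hypothesis. A loss of medium spiny neurons alone was not tested directly. Log2 fold changes in the list ranged from -3.94 to -0.39, with -1.86 (SE 0.10) for Ppp1r1b and -0.68 (SE 0.14) for Pdyn. The GABA list, with Gad1 at -0.50 (SE 0.08), had a median of -0.0038. These values argue against such a loss as the whole cause for these genes, but not as a part of it. Of the 10 splits of the libraries into 3 and 2, 1 gave as many calls, the real one with 3882. The highest other gave 29 and set WT replicates 1 and 2 against the rest. Each other split put WT and R6/1 libraries in the same group, which widens the spread, so few calls were likely there. So few splits also cannot give a share under 0.05, and the splits do not decide on chance.

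The rise of the developmental list was weighed against depth and neighbouring tissue. Its median was 0.762 after thinning (0.649 to 0.85 over 10 thinnings) against 0.816 before, with the same members. With the filter applied again to 1 thinning it was 0.615. Thinning keeps each library's expected proportions, so the median could hardly move toward 0 and does not decide on depth. In that thinning 9 members still rose, so the larger number of counts in R6/1 does not account for most of these calls. The larger of the medians of the cortical and subcortical marker lists was the subcortical one, -0.465 (bootstrap interval -0.758 to -0.09), but it was -0.18 without R6/1 replicate 2, -0.80 without R6/1 replicate 1, -0.30 without WT replicate 2 -0.014 with WT replicates 1 and 2 left out and 0.14 with the choroid plexus covariate. The cortical median of -0.93 was -1.62 without R6/1 replicate 1, -0.37 without R6/1 replicate 2, -0.45 without WT replicate 2 -1.01 with WT replicates 1 and 2 left out and -0.74 with the covariate. Library means of the tested members varied among WT libraries by 1.93 for the cortical and 0.495 for the subcortical list (0.457 with its untested member) and Slc17a7 reached 136 CPM in WT, so a small share of neighbouring tissue in the R6/1 samples stays open, as does the genotype.

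The fall of the clock list was weighed against a different time of day at collection, which the sources used here do not give. That explanation was taken to predict, with other members falling, a median above 0 for Arntl, Clock and Cry1. Their median was 0.0307 with an interval of -0.09 to 0.177 from their standard errors, so time of day and genotype cannot be told apart. Cry1 alone rose (log2 fold change 0.38, edgeR adjusted p = 0.0171).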
